A study of Mus musculus with 4 samples.

How the data were processed

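Kidneys of 4 groups of mice were profiled by droplet single-cell RNA sequencing: Lyz2-cre control and mKO (Rgmb floxed, deleted by Lyz2-cre), each after saline or 72 h after 20 mg/kg cisplatin, with 1 library per group. Per the labels, kidneys were perfused, digested with collagenase for 30 min and filtered at 40 µm, and 10x Genomics 3' libraries were made. The labels name the first genotype WT; it is called control here because the series title names Lyz2-cre mice as the control. How many animals went into each library is not given in the sources used here. Each deposited matrix holds raw UMI counts per gene and barcode, a count unit made by the authors with Cell Ranger 7.1.0 and the mm10 genome according to the submitters' processing notes. Each matrix has exactly 12000 barcodes and the same 33696 genes, of which 31961 IDs (94.85%) are in the GENCODE vM21 annotation of GRCm38 and 1735 are not; the annotation release used upstream is not given in the sources used here. All 384 symbols of the gene lists and cell markers were found.

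Library totals were 21.7e6, 19.6e6, 26.1e6 and 21.5e6 UMIs for control saline, control cisplatin, mKO saline and mKO cisplatin. The median mitochondrial share over all barcodes was 68.9%, 85.8%, 44.8% and 77.7%. Barcodes with at least 200 genes and at most 50% mitochondrial UMIs were kept: 3163 (26.4%), 1741 (14.5%), 6929 (57.7%) and 2925 (24.4%). Median depth of kept cells was 1969, 1977, 1212 and 1143 UMIs, and their median mitochondrial share 28.8%, 13.2%, 29.3% and 25.4%. Scrublet, as implemented in scanpy with an expected rate of 6%, marked 2, 0, 0 and 4 cells, under the 0.5% taken as the minimum for a working call, so no cell was removed as a doublet.

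Cells were scaled to 10000 UMIs and log-transformed, 2000 variable genes were chosen, and a graph on 30 principal components and 20 neighbours was clustered by the Leiden method at resolution 1.0 with seed 1, over all 4 libraries together (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). This gave 28 clusters. A marker counted as present in a cluster at 20 CPM or more, in at least 10% of its cells and at least 2-fold above the median cluster. Each class with at least 3 present markers was scored by the mean of its markers' CPM relative to the cluster highest for each marker. A cluster took the name of the best class if its score was at least 0.25, no class of another compartment passed 0.5 of it, and the 10 top genes held no more markers of another compartment; a shallow cluster needed a marker among them. Injured tubule did not count as another compartment in these rules, so a cluster with injury markers could keep a segment name. Loop of Henle cluster 3, for example, held Lcn2 and Spp1 among its 10 top genes. The injured tubule name also required Havcr1 or Krt20, and the erythroid and plasma names a marker among the 10 top genes. That gave 25 named and 3 unnamed clusters, and no dendritic cluster. The marker lists were written before the data were examined, as were the gene lists, the comparisons, the filters, the rule for named genes and all alternatives save one given in the closing section. The scoring rule for naming was set after the clusters had been seen, and 4 forms of it were tried.

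For the ratios, UMIs were summed over the cells of a class in each library and divided by the nuclear-encoded total (CPM). Tubule cells were taken as the union of proximal, injured, loop of Henle, distal convoluted, principal and intercalated classes, and macrophage and monocyte clusters were merged. Classes with fewer than 20 cells in a library were not compared. Single clusters had no such limit: macrophage cluster 18 held 14 control cisplatin cells. A gene was measured in a comparison when the 2 libraries held at least 20 UMIs together in that class. Intervals are exact 95% Poisson intervals for CPM, conditional binomial intervals for ratios and exact binomial intervals for shares. Where a library had 0 UMIs the ratio was computed against a floor of 3 counts in that library and is a bound. No p-value was computed, since cells of 1 kidney library are not replicates.

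Single genes were named by a fixed rule: at least 20 UMIs and 20 CPM in the higher library, a level in the class at least that of all other kept cells, and then the 12 highest and 12 lowest by the interval bound nearest 0. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, Gm-number, Rik, Xist and Y-linked genes were left out. The rule was applied to tubule and macrophage/monocyte-like cells for control cisplatin over control saline and for both mKO over control comparisons. Other genes are named as members of the 22 gene lists, as the deleted gene, or as the free-RNA marker. The lists were tubule injury, p53 response, proximal tubule transport, fatty acid oxidation, gluconeogenesis, cisplatin handling, NRF2 and metallothionein, necroptosis and pyroptosis, ferroptosis, efferocytosis, inflammatory cytokines, alternative activation and repair, interferon response, BMP and RGMb pathway, antigen presentation, complement, proliferation, matrix and fibrosis, endothelial activation, dissociation and stress, sex check and androgen-responsive genes. Each list's median log2 ratio was placed among 10000 random lists drawn from 20 expression bins.

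The ratios and list percentiles were tested on simulated data with known changes, built on the depths of 3 comparisons: control tubule cisplatin over saline, and mKO over control after cisplatin in tubule and in macrophage/monocyte-like cells. The intervals covered the set value for 96.0%, 95.8% and 96.4% of genes. Genes raised 2-fold were recovered in 92.0%, 90.0% and 86.0% of cases, and genes lowered 2-fold in 90.0%, 87.5% and 51.1%. Among lists with no set change, 3.5%, 4.5% and 6.5% fell outside the central 95%. The simulated counts were independent Poisson draws, the model that the intervals assume. These values therefore check the computation only. They do not cover counts clumped in single cells or list genes that vary together.

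Alternatives were a stricter filter (500 genes, 25% mitochondrial UMIs), no mitochondrial limit, Leiden resolutions of 0.5 and 2.0, each library clustered alone, CPM over all genes, TMM factors (edgeR 4.0.16 in R 4.3.3), the mean of each cell's CPM, a minimum of 100 UMIs or none, macrophage clusters only, proximal and injured tubule only, and Rgmb shares after thinning cells to 500 UMIs. Unnamed clusters were left out of all class comparisons. On GRCm38, Rgmb lies on chromosome 17 at 15803188 to 15831039 and Bap1 on chromosome 14 at 31251450 to 31259944. Reads were not used here, so no sequence was examined.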

Results

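Whole mouse kidneys were taken after saline, or 72 h after 20 mg/kg cisplatin, from Lyz2-cre control mice and from mice in which Lyz2-cre deletes floxed Rgmb in myeloid cells (mKO). Each of the 4 groups was a single 3' RNA library of 12000 barcodes. After filtering, 3163 cells were kept in control saline, 1741 in control cisplatin, 6929 in mKO saline and 2925 in mKO cisplatin, with median depths of 1969, 1977, 1212 and 1143 UMIs. Cell classes were named from marker genes, so each name below means cells that resemble that class. Cells in clusters that could not be named made up 4.87%, 4.02%, 27.1% and 3.18% of the 4 libraries in the same order.

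With 1 library per group, no difference below could be tested, and the intervals in brackets are exact Poisson or binomial 95% intervals that cover counting error only. Levels are CPM, the UMIs of a gene summed over the cells of a class and scaled by that class's total of nuclear UMIs. For most gene lists pooled over a class the median log2 ratio is given with the number of measured members at least 1.5-fold higher or lower. Values within single clusters are medians alone, and some rest on only 3 measured genes. The percentile places that median among 10000 random lists of matched expression, and describes these 4 libraries alone.

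Rgmb, which encodes a GPI-anchored BMP co-receptor, was detected in all 4 libraries, at 14.6 [12.2, 17.3] CPM in control saline, 18.8 [16.5, 21.2] in control cisplatin, 9.10 [7.63, 10.8] in mKO saline and 17.5 [15.2, 20.1] in mKO cisplatin. Over all kept cells the mKO library stood at log2 −0.10 [−0.38, 0.17] against control after cisplatin and at −0.68 [−1.04, −0.33] after saline. Most of this RNA came from outside the myeloid lineage: principal-like cells held 29.2, 29.4, 21.1 and 45.8 CPM, and intercalated-like cells 31.7, 32.4, 29.0 and 30.5 CPM. In macrophage/monocyte-like cells Rgmb had 4, 15, 11 and 1 UMIs, or 10.4, 7.15, 22.9 [11.4, 40.9] and 1.88 [0.0476, 10.5] CPM. The mKO to control ratio there was −1.93 [−7.32, 0.78] after cisplatin and 1.14 [−0.61, 3.25] after saline. Neutrophil-like cells had 0, 0, 0 and 11 Rgmb UMIs, and the 11 came from 3 of 23 cells; a count of 0 allowed up to 272, 4.28 and 171 CPM in the other 3 libraries, taken as 3 counts here and at each count of 0 below.

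The share of macrophage/monocyte-like cells with an Rgmb UMI was 1.82%, 6.15%, 4.08% and 0.448%, at median depths of 2595, 5156, 1771 and 833 UMIs. T/NK-like cells had 0%, 0%, 0% and 2.78% at 2794, 5303, 2489 and 4503 UMIs, where none seen allowed up to 6.98%, 13.04% and 5.66%. With 43, 23, 53 and 36 cells, that class sets no background level. Reads at the 3' end can come from outside the deleted part of the gene, so these levels neither show nor rule out the deletion.

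In control kidneys, tubule cells after cisplatin carried injury genes far above, and transport genes far below, their saline levels. Lcn2, an iron-binding protein shed by injured tubules, was at 3434 CPM after cisplatin and 3.52 CPM after saline, 977-fold higher (log2 9.93 [9.39, 10.53]). Havcr1 (KIM-1) was higher by 10.48 [7.999, 15.78] with 1 saline UMI, Krt20 by 9.55 [7.70, 12.60] with 2, and the cornified-envelope gene Sprr2f by 10.53 [8.68, 13.58] with 2. Spp1 was higher by 4.07 and Clu by 3.57. All 17 measured members of the tubule injury list were at least 1.5-fold higher, with a median of 3.05 at percentile 100. That median carries the cell mix: injured tubule-like cells went from 1.13% to 45.7% of tubule-like cells. By nuclear UMIs, principal-like cells went from 754668 of 7678184 to 3472445 of 8469631. No cisplatin over saline value is given within injured tubule-like cells, because the class changed cluster. The deep cluster 23 held 24 of 28 such cells in control saline and 37 of 38 in mKO saline, and the shallow cluster 8 held 454 of 485 in control cisplatin and 116 of 137 in mKO cisplatin. In proximal tubule-like cells the list stood at 3.82. Lif and Ccl20, both secreted cytokines, were higher by 6.13 [5.08, 7.45] and 5.89 [5.08, 6.85].

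The p53 response list was higher in all 16 measured members after cisplatin in control tubules, with a median of 2.65. Cdkn1a, which halts the cell cycle, was at 836 CPM against 18.2 (5.52 [5.28, 5.77]), Phlda3 at 5.27, Eda2r at 5.39, Gdf15 at 3.44 and Mdm2 at 2.23. In the interferon response list 14 of 15 measured genes were higher (median 3.52), among them Ifit1 (4.52), Isg15 (4.39) and Ifitm3 (4.26). The metal-binding genes Mt2 (3.95) and Mt1 (2.99) led the NRF2 and metallothionein list, higher in 9 and lower in 1 of 12 members. The matrix and fibrosis list was higher in 8 of 12 (median 0.93), with Ccn2 at 3.52 and Tgfb1 at 2.72.

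**Figure D1:**
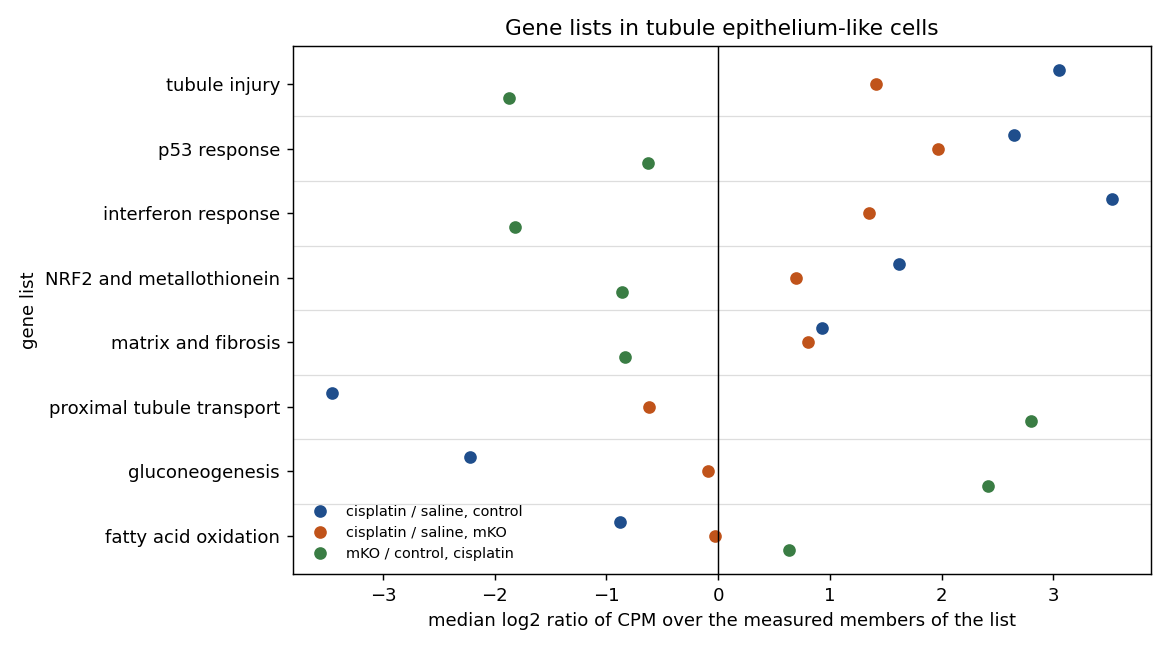
Median log2 ratio (horizontal axis) of 8 gene lists in tubule-like cells, with 1 dot per comparison for cisplatin over saline in control, cisplatin over saline in mKO, and mKO over control after cisplatin. The tubule injury list stands at 3.05, 1.41 and −1.87, and the proximal tubule transport list at −3.46, −0.62 and 2.80.

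Transport and metabolic genes of the proximal tubule moved the other way in control kidneys. All 16 measured members of the proximal tubule transport list were lower after cisplatin, with a median of −3.46 at percentile 0. Part of this is a change in the cells named: proximal tubule-like cells went from 66.2% to 7.91% of tubule-like cells, and the median was −2.34 over proximal and injured tubule-like cells together and −1.14 in proximal tubule-like cells. That class changed too: its 84 control cisplatin cells had 52 in the shallow cluster 0, while clusters 2, 11 and 14 went from 345, 183 and 127 cells to 6, 0 and 0. In mKO, cluster 0 held 930 of 2666 such cells after saline and 613 of 989 after cisplatin. Values for proximal tubule-like cells below carry this shift. Free proximal tubule RNA adds to the pooled ratios, since Kap in loop of Henle-like cells stood at 3359, 27.5, 6262 and 250 CPM in the 4 libraries. The phosphate transporter Slc34a1 was at 79.9 CPM against 2728 (−5.09 [−5.21, −4.98]), and Slc22a8, Slc22a6 and the endocytic receptor Lrp2 were at −5.31, −4.25 and −3.26. Miox, which oxidises inositol, was at 26.6 CPM against 1949 (−6.20 [−6.39, −6.01]), and Gatm, Slc7a13 and Inmt were at −5.52, −6.97 and −6.49. Gluconeogenesis genes were lower in 5 of 6 over all tubule-like cells (median −2.22), with G6pc at −4.32, Fbp1 at −3.20 and Pck1 at −1.80, but the list stood at −0.20 in proximal tubule-like cells. Fatty acid oxidation genes were lower in 13 of 16 and higher in 1 (median −0.88), but stood at 0.20 in proximal tubule-like cells, so the pooled drop in these lists was not told apart from the change in the cells named. Over all tubule-like cells Acaa1b was at −2.46 and Pdk4 at 1.86. In the cisplatin handling list the uptake and efflux transporters Slc22a2 and Slc47a1 were at −4.36 and −2.97, the DNA repair gene Ercc1 was at 2.68, and the median was −0.38 (2 of 10 higher, 5 lower).

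In control tubules the necroptosis and pyroptosis list had a median of 0.80 with 6 of 9 genes higher and 1 lower, among them Mlkl at 3.32 [1.86, 5.26]. The ferroptosis list was at 0.09 (below 0 with TMM scaling), with Acsl4 at 2.03 and Gpx4 at −0.75. The proliferation list was at 0.48 with 6 of 14 genes higher and 2 lower, and the BMP and RGMb pathway list at 0.43 with 6 of 17 higher and 1 lower, including Smad1 at 1.21. The dissociation and stress list was at 0.37 with 5 of 14 higher and 1 lower, but below 0 in 4 classes: −0.12 in proximal, −0.12 in loop of Henle, −0.23 in principal and −0.23 in intercalated-like cells. Handling of the tissue and stress in the animal were not told apart in this list, here or below. The BMP and RGMb pathway list also fell below 0 in loop of Henle and principal-like cells (−0.23 and −0.27). These pooled medians carry the cell mix. The androgen-responsive list was lower in all 4 genes (median −3.77), including Cyp2e1 at −5.62. The 4 sex check genes had a median of −0.40 with none past 1.5-fold.

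Immune cells also took up more of the control library after cisplatin. Neutrophil-like cells were 10.5% [9.11, 12.1] of kept cells against 0.253% [0.109, 0.498] after saline, 41.6-fold higher. Macrophage/monocyte-like cells were 14.0% [12.4, 15.7] against 5.22% [4.47, 6.05], 2.69-fold higher. T/NK-like cells were 1.32% against 1.36%, and endothelial-like cells 7.41% against 4.52%. Proximal tubule-like cells were 4.83% against 52.0% and injured tubule-like cells 27.9% against 0.885%. These 2 tubule classes are set apart by the same transport and injury genes that differ above, so their shares restate those gene levels. At Leiden resolution 0.5 the injured ratio was log2 0.58 and the loop of Henle ratio −0.45. Loop of Henle-like cells were 18.3% against 8.88%, held mainly by the deeper cluster 6 after saline and by the shallow cluster 3 after cisplatin, in both genotypes.

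**Figure D2:**
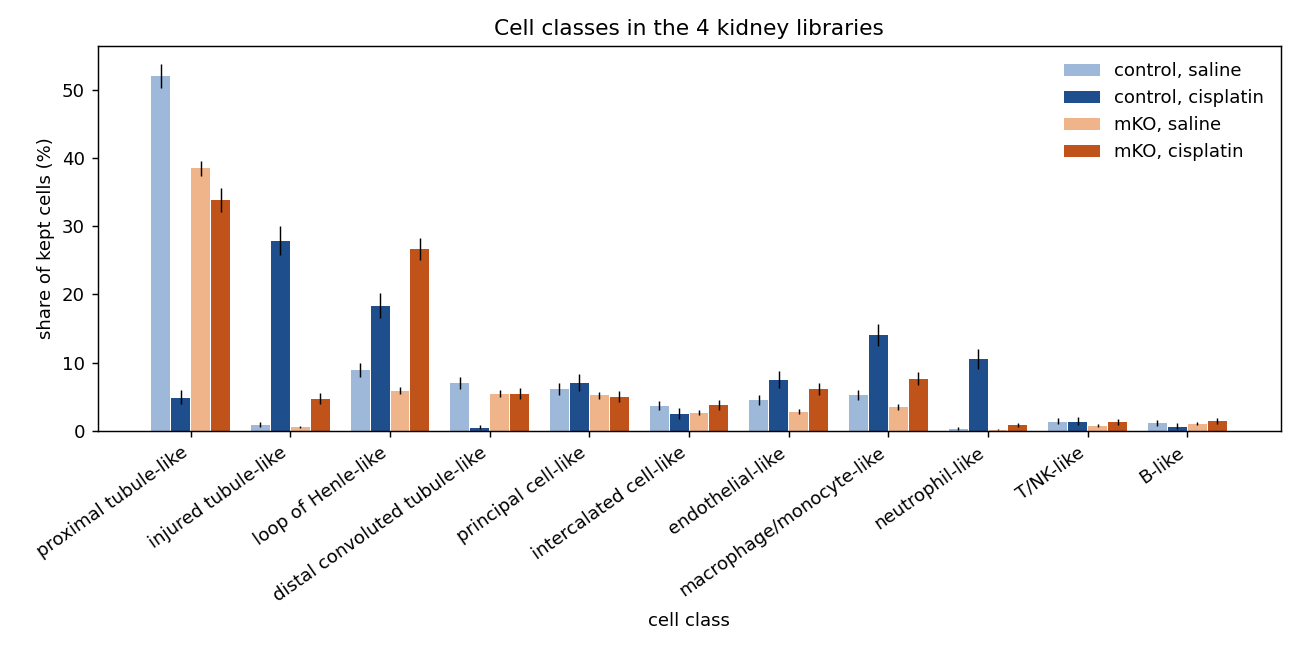
Share of kept cells in % (bar height, with exact 95% binomial intervals) for 11 cell classes in each of the 4 libraries. Neutrophil-like cells reach 10.5% in control cisplatin and stay at or under 0.786% in the other 3 libraries.

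Macrophage/monocyte-like cells of the control kidney differed in antigen presentation and stress genes after cisplatin. Antigen presentation genes were lower in 9 of 11 and higher in 2 (median −2.13, percentile 0): H2-Aa was at 1012 CPM against 6450 (−2.67), H2-Eb1 at −2.91 and the class II activator Ciita at −3.52, while Cd274 (PD-L1) was at 2.97 and Cd80 at 2.10. The dendritic cell markers Xcr1 and Cd209a were lower too, at −5.84 [−8.97, −3.80] and −4.03 [−5.02, −3.13], and no dendritic cluster was named, so the class II change was not told apart from a loss of dendritic cells. The alternative activation and repair list was higher in 7 of 9 and lower in 1 (median 0.93), with the lipid carrier Fabp5 at 3.54. The NRF2 and metallothionein list was higher in 7 of 11 (median 0.97), led by the cystine transporter Slc7a11 at 2.71 and Gsr at 2.37. Slc7a11 is also high in neutrophil-like cells, and S100a8 and S100a9 rose with it here, from 0 UMIs to 886 and 248 CPM. Among the 12 highest genes were Vcan at 6.09 [4.24, 9.14], Thbs1 at 3.38 [2.79, 4.04] and Fn1 at 548 CPM against 57.0. AA467197 was at 386 CPM against 0 UMIs, at least 49.7-fold higher with the floor of 3 counts in that library.

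Chemokines split in these cells. Inflammatory cytokines were higher in 6 of 14 and lower in 4 (median 0.49): Il1a was at 5.13 [2.63, 10.44] with 1 saline UMI, and Osm at 1.67, but Ccl4 was at 449 CPM against 4057 (−3.17) and Ccl3 at −2.23. Cxcl9, a chemokine gene outside that list, was at −6.61 [−9.71, −4.66]. Efferocytosis genes had a median of 0.38 (5 of 14 higher, 2 lower), below 0 when each cell's CPM was averaged, with the engulfment receptor Lrp1 at 1.97. Interferon genes stood at 0.42 (6 of 15 higher). Complement genes were lower in 5 of 8 and higher in 2 (median −0.81, just above 0 when each cell's CPM was averaged), and dissociation and stress genes lower in 12 of 14 (median −1.09), including Egr1 at −2.68. Within clusters 13, 16 and 18 the complement list stood at 1.43, 2.62 and 0.33, opposite to the pooled value, alternative activation at 0.67, 0.48 and 0.06, inflammatory cytokines at 0.95, 0.21 and 1.48, interferon at 0.83, 0.41 and 0.01, and antigen presentation at −2.16, −1.64 and −1.21. Within clusters 16 and 18 NRF2 and metallothionein genes stood at 0.85 and 0.43, efferocytosis at 0.75 and 0.64, and dissociation at −0.51 and −0.91. These ratios mix 3 clusters: macrophage cluster 18 held 46.7% of the cells of the class after saline, and monocyte cluster 16 held 49.6% after cisplatin. By nuclear UMIs, which set the pooled ratios, cluster 16 gave 126263 of 385718 after saline and 1854974 of 2099093 after cisplatin. Cluster 18 held only 14 cells after cisplatin. Chil3, at 5.54 in the class, is a monocyte marker, and its levels within clusters were not compared.

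In mKO kidneys cisplatin went with a clear p53 response, and over all tubule-like cells with less injury signal and a smaller drop in transport genes than in control. All 16 measured p53 genes were higher in tubule cells (median 1.97): Cdkn1a was at 384 CPM against 13.9 (4.79 [4.56, 5.02]), Phlda3 at 4.90, Gdf15 at 2.16, Ccng1 at 1.95 and Mdm2 at 1.90. Tubule injury genes were higher in 13 of 16 (median 1.41), with Lcn2 at 4.43, Spp1 at 2.63, Havcr1 at 2.44 [1.51, 3.48] and Krt20 at 0.62 [−0.07, 1.32]. Lcn2, Havcr1 and Krt20 started from higher saline levels in mKO than in control, so part of their smaller rise lies there. Control saline held few UMIs of Havcr1 and Krt20. The injury list stood at 1.05 in proximal tubule-like cells. Proximal tubule transport genes were lower in 9 of 16 (median −0.62), with Slc34a1 at 1603 CPM against 3127 (−0.96), Slc22a6 at −1.61 and Slc5a12 at −0.24, but the list stood at −0.03 in proximal tubule-like cells. Interferon genes were higher in 11 of 15 and lower in 1 (median 1.35), including Isg15 at 2.13, though the list stood at −0.15 in proximal, 0.24 in loop of Henle, 1.19 in principal and −0.21 in intercalated-like cells. NRF2 and metallothionein genes were higher in 9 of 12 (median 0.70), including Mt1 at 1.42.

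Over all mKO tubule-like cells the metabolic lists had medians near 0 after cisplatin. Fatty acid oxidation genes had a median of −0.03 (2 of 16 higher, 2 lower), and gluconeogenesis genes −0.09 (2 of 6 lower), both just above 0 with CPM over all genes, with Pck1 at 0.29 and G6pc at −1.20. In proximal tubule-like cells they stood at 0.31 and 0.27, and values for other classes are left out because of the free RNA given above. The platinum uptake transporter Slc22a2 was at −1.31. The matrix and fibrosis list had a median of 0.80 (7 of 12 higher, 1 lower), with Tgfb1 at 1.86 and Ccn2 at 0.79, but stood at −0.0084 over proximal and injured tubule-like cells only and at −0.37 in loop of Henle-like cells. The dissociation and stress list was at 0.58 over all tubule-like cells and in proximal tubule-like cells, and at −0.13, 0.12 and −0.14 in loop of Henle, principal and intercalated-like cells. The androgen-responsive genes were again lower in all 4, with Cyp2e1 at −1.80.

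The median ratio of a list in mKO minus that in control was −1.64 for tubule injury, −0.68 for p53, 2.84 for proximal tubule transport, −2.17 for interferon and −0.92 for NRF2 and metallothionein in tubule cells. These pooled differences carry the cell mix. In proximal tubule-like cells they were −2.77 for tubule injury, −0.51 for p53, 1.11 for transport and −1.27 for NRF2 and metallothionein, with no control value for interferon. In loop of Henle, principal and intercalated-like cells they were −0.80, 0.0399 and −0.86 for p53 and −1.745, −1.542 and −3.505 for interferon. The control interferon list stood at 1.98, 2.73 and 3.29 in these 3 classes, with 43 intercalated-like cells in control cisplatin. None of these differences between genotypes was tested, because each rests on 1 library per group.

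In mKO kidneys macrophage/monocyte-like cells were 7.62% [6.69, 8.65] of kept cells after cisplatin against 3.54% [3.11, 3.998], 2.16-fold higher (log2 1.11 [0.84, 1.38]). The control ratio was 1.43 [1.14, 1.72], so the intervals overlap. Under the stricter filter control stood at 0.80 [0.38, 1.22] and mKO at −0.14 [−0.67, 0.38], with no overlap before rounding. These intervals cover counting error only, so whether they overlap does not decide if the genotypes differ. T/NK-like cells were at 0.69 [0.03, 1.32] in mKO and −0.04 [−0.84, 0.72] in control. Unnamed cells were 27.1% of mKO saline and 3.18% of mKO cisplatin, which alters all mKO shares of kept cells here. Among immune-like cells of mKO, T/NK-like cells were 11.15% after cisplatin and 13.95% after saline. Neutrophil-like cells were 0.786% [0.499, 1.18] against 0.173% [0.0895, 0.302], 4.54-fold higher. Loop of Henle-like cells were 4.51-fold higher, at 26.6%, but among tubule-like cells they were 33.6% against 10.1%, a smaller rise. Injured tubule-like cells were 4.68% of kept cells against 0.548%, with the caveat on injury genes given above. In macrophage/monocyte-like cells the proliferation list was higher in 7 of 10 genes (median 1.12), with Ube2c at 2.99 and Top2a at 1.60, though within clusters 13, 16 and 18 it stood at 1.62, −1.25 and 1.57. Class II genes were modestly lower (H2-Aa and Cd74 both −0.58, list median −0.58), but within clusters 13, 16 and 18 the list stood at 0.47, −0.63 and −0.53. Cluster 13 went from 47.3% to 72.6% of the cells of the class, cluster 16 from 21.2% to 15.7% and cluster 18 from 31.4% to 11.7%. By nuclear UMIs, clusters 13, 16 and 18 gave 98105, 236610 and 196703 of 531418 after cisplatin. Ccl5 and Ccl7 were at −3.54 and −2.73. The inflammatory cytokine list had a median of −0.12 and the efferocytosis list −0.07 (above 0 with TMM or with CPM over all genes), where Lrp1 was at 0.96 and Ucp2 at 0.84. Within the same clusters the efferocytosis list stood at −0.72, 0.49 and 0.01, and the inflammatory list at 0.09 in cluster 16 and −0.02 in cluster 18.

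Between the 2 cisplatin kidneys, tubule cells of mKO pooled together held more transport and less injury RNA than control. Pooled values carry the cell mix by UMIs. Principal-like cells gave 1442558 of 8961753 nuclear tubule UMIs in mKO and 3472445 of 8469631 in control, and proximal tubule-like cells 3574837 and 228072. Within proximal tubule-like cells Slc34a1 was at 3666 CPM in mKO and 903 in control, a smaller gap than the pooled one below. Slc34a1 was at 1603 CPM in mKO against 79.9 in control (4.33 [4.21, 4.44]), Miox at 5.16 [4.97, 5.36], the anion transporters Slc22a8, Slc22a30 and Slc22a28 at 4.73, 5.13 and 7.09, and the oxidoreductases Rdh16f2 and Cyp4a12a at 5.19 and 5.45. All 16 measured transport genes were at least 1.5-fold higher (median 2.80, percentile 100, and 2.12 over proximal and injured tubule-like cells together, 1.11 and 1.18 in each), as were 5 of 6 gluconeogenesis genes (median 2.41) and 11 of 16 fatty acid oxidation genes (median 0.63, 1 lower). In proximal and injured tubule-like cells alone, gluconeogenesis stood at 0.22 and 1.14 and fatty acid oxidation at −0.10 and −0.14. Cisplatin handling genes were higher in 4 of 10 and lower in 1 (median 0.43), with Slc22a2 at 3.51.

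Injury genes were lower in 15 of 17 (median −1.87, percentile 0, and −2.10 and −0.41 in proximal and injured tubule-like cells) in mKO tubules after cisplatin. Lcn2 was at −4.09 [−4.16, −4.02], Havcr1 at −5.03 [−5.46, −4.63], Krt20 at −5.42 [−5.90, −4.97] and Crct1 at −7.44 [−10.50, −5.58] with 2 mKO UMIs. The secreted factors Ccl20 and Lif were at −5.53 and −3.73, the AP-1 gene Fosl1 at −3.45 and the replication gene Cdt1 at −3.70. p53 genes were lower in 11 of 16 (median −0.63, but 0.12 in injured tubule-like cells), with Cdkn1a at −1.12 and Gdf15 at −1.12, while Ccng1 stood at 0.09. Interferon genes were lower in 13 of 15 and higher in 1 (median −1.82), NRF2 and metallothionein genes in 8 of 12 with 1 higher (median −0.86), and matrix genes in 9 of 12 (median −0.83), with Ccn2 at −3.10. Proliferation genes were lower in 9 of 14 (median −1.16), including Mcm5 at −2.15. Necroptosis and pyroptosis genes were lower in 4 of 9 (median −0.51), with Mlkl and Ripk3 both at −2.54. The ferroptosis list stood at 0.11 (below 0 when each cell's CPM was averaged), the BMP and RGMb pathway list at −0.18 and the dissociation and stress list at −0.20. Within classes some of these differed in sign: the BMP and RGMb pathway list stood between 0.08 and 0.26 in the 5 classes with a value, dissociation at 0.94 in injured tubule-like cells, interferon at 0.38 in proximal tubule-like cells, and proliferation at 0.10, 0.12 and 0.91 in injured, loop of Henle and intercalated-like cells. That interferon value is weak, since it rests on 84 control cells with 228072 nuclear UMIs against 3574837 in mKO.

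The immune compartment was smaller in the mKO cisplatin library. Neutrophil-like cells made up 0.786% of kept cells against 10.5%, a log2 ratio of −3.74 [−4.43, −3.11], and among immune-like cells 7.12% against 39.7%. Macrophage/monocyte-like cells were at −0.88 [−1.15, −0.61] (further below 0, outside that interval, under the stricter filter), T/NK-like cells at −0.10 [−0.90, 0.72], B-like cells at 1.15 [0.16, 2.26] and endothelial-like cells at −0.28 [−0.61, 0.06]. Proximal tubule-like cells were 33.8% against 4.83%, and injured tubule-like cells 4.68% against 27.9%, which again restates the gene levels above. The size of the proximal difference depended much on the filter and the clustering, as given in the closing section, though its sign held. At Leiden resolution 0.5 the injured ratio was log2 −0.50 [−1.08, 0.10] instead of −2.57. Distal convoluted tubule-like cells were 5.40% against 0.460%. With 1 kidney library on each side, a difference between animals cannot be told from one of genotype.

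Macrophage/monocyte-like cells of the mKO cisplatin library held less Il1b and Ccl2 and more class II RNA than those of control. They were also shallower, with medians of 833 UMIs and 21.7% mitochondrial UMIs against 5156 and 4.39% in control. Il1b was at 933 CPM against 2181 (−1.22 [−1.36, −1.09]), Ccl2 at −1.73, Ccl7 at −2.76, Il1a at −3.27, Il6 at −1.96, Ptgs2 at −1.89 and Osm at −1.83. The inflammatory cytokine list was lower in 8 of 14 and higher in 5 (median −1.02, percentile 0, and further below 0 when each cell's CPM was averaged), the higher genes including Ccl4 at 2.46, Ccl5 at 2.40 and Ccl3 at 1.59. Antigen presentation genes were higher in 7 of 11 and lower in 2 (median 1.51, percentile 100), with H2-Eb1 at 2.08, H2-Aa at 1.81 and Ciita at 1.70, against Cd274 at −1.85 and Cd80 at −1.62. NRF2 and metallothionein genes were lower in 10 of 11 (median −1.23), with Slc7a11 at −2.32 and Hmox1 at −1.11, and within clusters 16 and 18 the list stood at −0.97 and −0.43. The neutrophil genes S100a8 and S100a9 again moved with Slc7a11, from 886 and 248 CPM in control to 7.53 CPM and 0 UMIs in mKO. Proliferation genes were higher in 10 of 13 (median 1.56), with Stmn1 at 2.17, Birc5 at 2.29 and Mki67 at 1.85.

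Efferocytosis genes were lower in 6 of 14 and higher in 1 (median −0.53), with Mertk at −0.96, Lrp1 at −0.64 and the ligand Gas6 at 1.66 in macrophage/monocyte-like cells of mKO after cisplatin. The alternative activation and repair list was at −0.40 (2 of 10 higher, 3 lower), but at 0.48 with macrophage clusters only and −0.0729 with no minimum of UMIs, with Fabp5 at −2.81 and Cd63 at 1.94. Complement genes were higher in 4 of 8 and lower in 3 (median 0.60), with Cfp at −1.46 and C1qa, a macrophage marker, at 0.89. Interferon genes were at −0.11, the BMP and RGMb pathway list at −0.20, and dissociation and stress genes higher in 9 of 14 (median 0.85). Among single genes, Ccl17 was at 13.2 CPM against 275 (−4.38 [−5.70, −3.33]), Il1rn at −4.66 [−7.71, −2.78] with 2 mKO UMIs, Uck2 at −2.84 and Ecm1 at −3.28. Cadm1 and Slc15a2 were at 3.58 and 2.79. Retnla had 166 UMIs in mKO and 0 in control, all of them in 1 cell of 223.

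**Figure D3:**
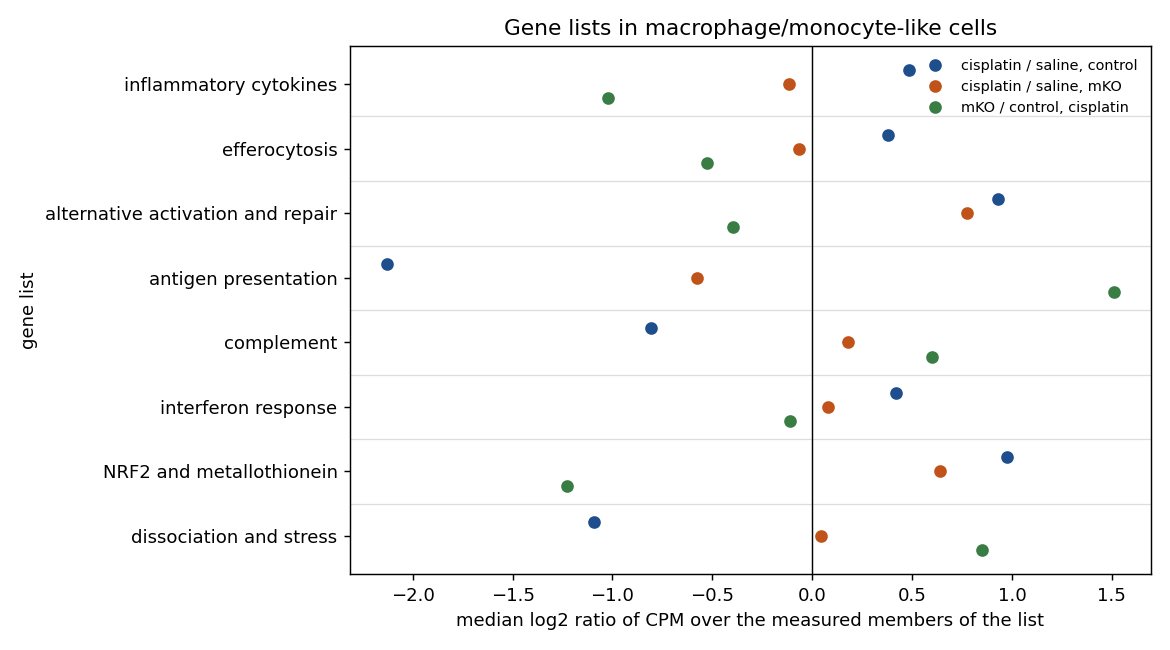
Median log2 ratio (horizontal axis) of 8 gene lists in macrophage/monocyte-like cells, with 1 dot per comparison for cisplatin over saline in control, cisplatin over saline in mKO, and mKO over control after cisplatin. The antigen presentation list stands at −2.13, −0.58 and 1.51.

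The cluster mix differed here too. Shallow macrophage cluster 13 held 72.6% of the mKO cells and 44.7% of the control cells of the class after cisplatin, and monocyte cluster 16 held 15.7% and 49.6%. The pooled ratios weigh clusters by UMIs. Cluster 16 gave 236610 of 531418 nuclear UMIs in mKO and 1854974 of 2099093 in control, so the pooled control level is mostly that of monocyte-like cells. Cluster 18 held only 26 mKO and 14 control cells. Within clusters 13, 16 and 18 the inflammatory list stood at −0.86, −1.28 and −1.39 and the antigen presentation list at 1.52, 0.64 and 0.82, while the complement list stood at −0.32, −2.59 and −0.28, opposite to the pooled value. The proliferation list stood at 1.44, −0.39 and 3.08, and the alternative activation list at 0.20, −0.35 and −0.18. Within clusters 16 and 18 efferocytosis stood at −0.73 and −0.53 and dissociation at 0.28 and 0.82. The marker Cd209a, at 4.03, belongs to dendritic cells, for which no cluster was named, so the class II difference was not told apart from their number.

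After saline, the mKO and control tubules were close in most lists, and 1 gene stood far apart. Bap1, a nuclear deubiquitinase, was at 2590 CPM in mKO tubule cells against 17.6 in control (7.20 [6.96, 7.46], 147-fold). Over all kept cells it stood at 2415 CPM in mKO saline and at 15.8, 12.4 and 16.4 CPM in control saline, control cisplatin and mKO cisplatin. It was raised in every class measured in that library, from 256 CPM in erythroid-like cells to 7954 in injured tubule-like cells. Car1 (6.85 [5.49, 8.73], 4 control UMIs) and Eddm3b (5.83 [4.90, 6.96]) followed, at 54.7 and 58.0 CPM over all kept cells of mKO saline and at most 0.540 and 3.67 CPM elsewhere.

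**Figure D4:**
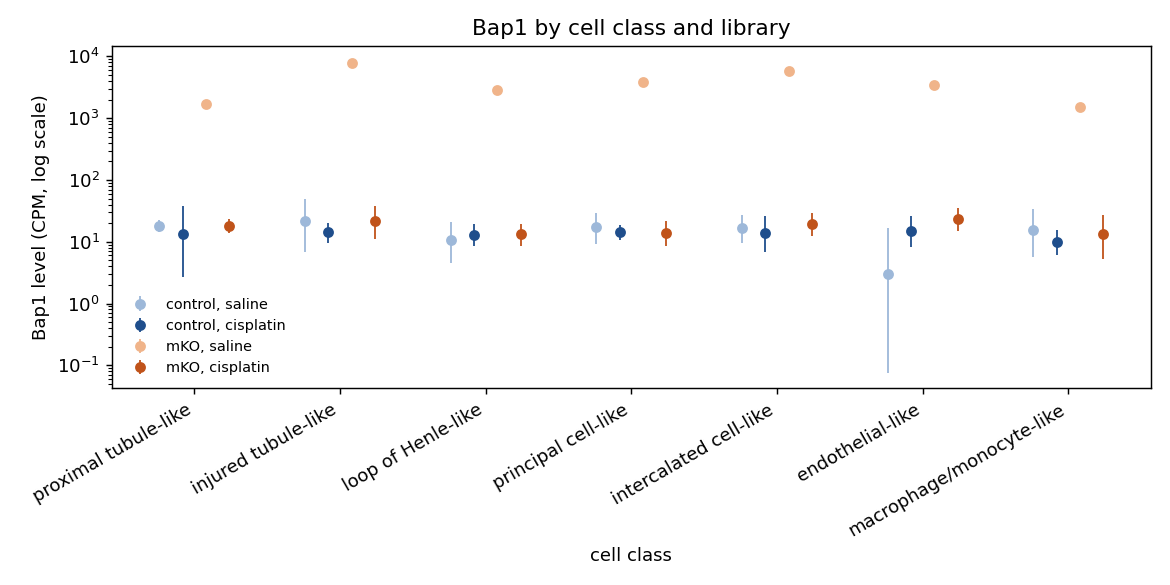
Bap1 level in CPM (logarithmic axis) in 7 cell classes of each of the 4 libraries, with 95% Poisson intervals. The mKO saline library lies far above the other 3 in each class shown, for example 1707 CPM in proximal tubule-like cells.

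Among the remaining tubule genes after saline, Rnase4 (2.89), Ccl28 (2.37) and Cyp4a12a (1.69) were higher in mKO, and Nrxn3 (−2.59), Guca2a (−1.52) and Ctsl (−1.09) lower. Tubule injury, proximal tubule transport, p53 and fatty acid oxidation lists had medians of −0.07, 0.11, 0.04 and −0.04, near enough to 0 that 3 of them (all but p53) changed sign with another scaling. The interferon list was at 0.38 (4 of 14 higher) and the proliferation list at −0.60 (6 of 12 lower), above 0 when each cell's CPM was averaged. Macrophage/monocyte-like cells were 3.54% of mKO cells against 5.22% (−0.56 [−0.85, −0.27]), but unnamed cells were 27.1% and 4.87%, and among immune-like cells the shares were 64.5% and 65.7%. Neutrophil-like cells stood at −0.55 [−1.96, 0.95].

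In macrophage/monocyte-like cells after saline, Ccl5 was at 351 CPM in mKO against 36.3 in control (log2 3.28, but −0.78 with macrophage clusters only), the growth factor Nrg1 at 3.17 [1.72, 5.11] and Slc15a2 at 2.19 [1.41, 3.06]. Lower genes were Agmo (−1.89), Vcam1 (−1.78), Rhob (−1.53), the heat-shock gene Hspa1a (−1.34) and Cxcl2 (−0.74). Inflammatory cytokines were lower in 4 of 12 and higher in 1 (median −0.47), and dissociation and stress genes had a median of −0.44 (3 of 14 lower). Within clusters the inflammatory list stood at −1.11 in 16 and −0.02 in 18, and the dissociation list at 0.44, −0.57 and −0.21 in 13, 16 and 18. Free RNA differed between libraries: the proximal tubule gene Kap stood at 5924, 16.2, 10450 and 303 CPM in these cells, against 64660, 23180, 80840 and 13560 CPM in proximal tubule-like cells, so tubule genes are not reported for them.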

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

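The tests in this part were chosen after the patterns had been seen, and each prediction was written before the tested value was computed, except that the test of free neutrophil RNA in other cell classes was written after S100a8 and S100a9 had been seen, and the p53 medians within clusters had no prediction.

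The share of intercalated-like cells moved in opposite directions with cisplatin in the 2 genotypes, by log2 0.49 [0.13, 0.83] in mKO and by −0.57 [−1.11, −0.05] in control, which is what brought it up. The difference is 1.06 and was not tested, because each share comes from 1 library. It depended on the processing: the control value was 0.71 when each library was clustered alone and the mKO value −0.43 under the stricter filter. Among tubule-like cells the share was 4.67%, 4.05%, 4.61% and 4.75% in control saline, control cisplatin, mKO saline and mKO cisplatin, with overlapping intervals. Unnamed cells were 27.1% of mKO saline and 3.18% of mKO cisplatin, which alters the share of all kept cells.

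After cisplatin the mKO library held more proximal tubule-like and fewer neutrophil-like cells than control. A kidney that cisplatin had not reached would lack the p53 response, but in loop of Henle-like cells 10 of 12 measured p53 genes were higher in mKO after cisplatin, with a median log2 ratio of 1.48 at percentile 100. These cells lay mainly in cluster 6 after saline (305 of 409) and in cluster 3 after cisplatin (624 of 778), but within clusters 3 and 6 the median was 1.98 and 1.48. If depth and barcode quality made the neutrophil difference, it was predicted to shrink towards 0 under the stricter filter, but it stood at −3.26 [−3.96, −2.63]. Neutrophil-like cells had medians of 3942 UMIs and 3.69% mitochondrial UMIs in control cisplatin, and 2719 and 7.37% in mKO cisplatin. That filter takes out shallow or mitochondrial-rich cells, so this value cannot decide, and it leaves the proximal tubule-like share unaddressed. The p53 values argue against a kidney that cisplatin had not reached as the whole cause. Variation in injury between animals and an effect of genotype cannot be told apart, since there is 1 library per group.

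The 12 lowest genes of mKO macrophage/monocyte-like cells after cisplatin had a pooled median log2 ratio of −3.43 against control. Within single clusters the median was −2.28, or 66.4% of the pooled value, so a different mix of macrophage and monocyte clusters may carry part of it and how much stays open. Of the 12, 2 (Il1rn and Wfdc21) were over 5 times higher in neutrophil-like cells, but genes higher in the other cells had been left out before the 12 were chosen, so that number excludes nothing. Free RNA would also enter other cells of the control cisplatin library. There, S100a8 and S100a9 allowed neutrophil RNA at most 0.115% of the total in proximal tubule, loop of Henle, endothelial and T/NK-like cells, which would bring at most 1.02% of the level of any of the 12. That argues against free neutrophil RNA as the cause. S100a8 and S100a9 stood higher in macrophage/monocyte-like cells themselves (886 and 248 CPM). Neutrophil-like cells of that library held 39020 and 51900 CPM, with S100a9 the higher, so neutrophil RNA alone would not give this balance. Whether part of it came from cells captured with neutrophils was not tested. An effect of genotype was not tested apart from these.

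Bap1 stood far above the other 3 libraries in every measured class of the mKO saline library. Free RNA in the suspension would weigh most in shallow cells, but Bap1 was higher in the deepest 102 than in the shallowest 102 loop of Henle-like cells of that library, by log2 1.88 [1.51, 2.27], while the proximal tubule genes Kap and Slc34a1 went the other way (−2.42 and −2.49). That argues against free RNA as the whole cause. A sequence variant or insertion in the animal tissue of that 1 library may be the source and stays open. Reads were not used, so other sources confined to that library stay open too. Bap1 was not raised in mKO cisplatin (16.4 CPM over all kept cells), so the Rgmb deletion alone does not account for its level.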

How the results depend on the processing

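Ratios are log2, with the value as reported first. Of the main results, 32 alternative values for cell shares, 94 for lists and 2 for Rgmb stayed within the counting interval, and 13, 26 and 6 moved, 1 of them (alternative activation) with a change of sign. For a list, that interval runs from the median of its members' lower bounds to the median of their upper bounds. It is as wide as that of a typical member and is not an interval of the list median, so staying within it is a loose criterion. Among the remaining results, 1412 gene values, 1531 list values and 167 share values stayed within it, 216, 217 and 61 moved, and 4, 9 and 19 went from a clear direction (an interval apart from 0, or a list at least 1.5-fold away and outside the central 95% of random lists) to the other sign. Counting values near 0 too, 4 of 1632 gene, 119 of 1757 list and 37 of 247 share values changed sign. The lists reported for each class were chosen after an earlier run over all lists had been seen. No paired analysis was possible because each group is 1 library with no pairing, and for the same reason the planned counts of genes at least 2-fold apart are not given. Where no reason is stated, the cause was not tested.

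The stricter filter removed shallow and mitochondrial-rich cells. Proximal tubule-like shares moved to −4.92 in control with cisplatin, 4.30 in mKO over control after cisplatin and 0.12 after saline (from −0.43), and the injured share in control to 3.56. Macrophage/monocyte-like shares moved from 1.43 to 0.80 in control, from 1.11 to −0.14 in mKO and from −0.88 to −1.67 in mKO over control after cisplatin, so under this filter macrophage/monocyte-like cells were no longer a larger share of mKO after cisplatin than after saline. In mKO over control after cisplatin, loop of Henle changed from 0.54 to −0.16 and principal from −0.52 to 0.73; after saline, loop of Henle went to 0.36 and distal convoluted tubule to 0.25. The intercalated share in mKO with cisplatin went from 0.49 to −0.43, the control p53 list to 2.25 and the saline interferon list in loop of Henle-like cells from 0.64 to −0.20.

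With no mitochondrial limit, proximal tubule-like shares stood at −2.93 (control), 2.16 (mKO over control, cisplatin) and 0.30 (saline), the control injured share at 6.52 and the saline intercalated share at 0.29 (from −0.45). The injury list stood at 3.67 in control and −2.19 in mKO over control after cisplatin, and the transport list at −4.78 and 4.07.

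At Leiden 0.5 the control injured share was 0.58 instead of 4.98 and that of mKO over control −0.50 instead of −2.57, the control loop of Henle share changed from 1.04 to −0.45 and the saline distal convoluted share from −0.37 to 1.32. At Leiden 2.0 saline shares of proximal tubule and loop of Henle were 0.16 and 0.0223 (from −0.59), the principal share in mKO over control after cisplatin 0.19, the control p53 list 2.31, the transport list −3.11 and 2.45, and the injury list −1.84 in mKO over control. Tubule shares therefore depend on how clusters are drawn.

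With each library clustered alone, some lacked an injured, neutrophil or other named cluster, so the injured share and several others have no value there. Proximal tubule-like shares were −2.35 (control), 1.76 (mKO over control, cisplatin) and 0.0192 (saline). Saline loop of Henle and distal convoluted shares were 0.20 and 0.18, intercalated shares 0.71 in control (from −0.57) and −0.28 in mKO over control after cisplatin (from 0.61), and the injury list 3.78 and −2.53.

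No scaling changed the sign of a main list (tubule injury, p53, transport and the macrophage lists of mKO over control after cisplatin), though lists with medians near 0, such as ferroptosis, did change. CPM over all genes put the control injury list at 3.26, and TMM put it at −1.83 for mKO over control. The mean of each cell's CPM put the transport list at −3.19 and 1.96, and, for mKO over control after cisplatin, injury at −2.06, p53 at −1.01 and inflammatory cytokines at −1.99 (from −1.02). There Btla changed from 3.86 to −0.31 and Mgp from −3.68 to 0.10, the saline tubule proliferation list from −0.60 to 0.15, the control complement list from −0.81 to 0.0525 and the mKO macrophage NRF2 list from 0.64 to −0.31. The median of all tubule genes shifted by −0.18 (control) and −0.16 (mKO) with TMM, by 0.21 and 0.0910 with all genes, and by −0.14 and −0.25 with cell means; in macrophage/monocyte-like cells by 0.11 and 0.0886 with TMM, by 0.22 and 0.0924 with all genes and, with cell means, by −0.23, −0.40 and −0.21 (mKO over control, cisplatin).

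With macrophage clusters only, complement changed to 0.52 in control and to −0.31 (from 0.60) in mKO over control after cisplatin, alternative activation there from −0.40 to 0.48, NRF2 in mKO with cisplatin to −0.17 and saline Ccl5 from 3.28 to −0.78; leaving out monocytes is what this setting does. With no minimum of UMIs alternative activation stood at −0.0729. In proximal and injured tubule only, the injury list was 3.61 and −2.44, p53 3.01 and −0.91, transport −2.34 and 2.12, the mKO matrix list −0.0084 (from 0.80) and saline Spink8 0.57 (from −0.86).

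The planned repeat with predicted doublets kept was void, since none were removed. Removing the highest 6% of doublet scores, chosen after seeing the data, took out 190, 104, 416 and 176 cells, and put the control injured share at 4.11 and the saline tubule proliferation list at 0.0874.

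Depth limits what Rgmb can show. In cells of at least 500 UMIs, thinned to 500, its shares fell from 3.64%, 9.54%, 1.70% and 5.09% to 0.474%, 0.403%, 0.289% and 0.406%. In macrophage/monocyte-like cells they went from 1.82% to 0.606% in control saline, from 6.64% to 0 in control cisplatin and from 4.08% to 0.408% in mKO saline, while mKO cisplatin had 1 such cell and kept its share.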

Other observations

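The p53 response to cisplatin was not limited to the proximal tubule. In loop of Henle-like cells the list median was 2.28 in control and 1.48 in mKO (1.75 and 1.98 within cluster 3, 2.24 and 1.48 within cluster 6), and in principal-like cells 2.27 and 2.31, with mKO over control at −0.44 and −0.39 after cisplatin. In endothelial-like cells p53 genes were higher in 11 of 14 in control (median 1.37) and in 10 of 14 in mKO (median 1.46), with Cdkn1a at 1.32 and 1.36, Bax at 1.35 and 1.83 and Phlda3 at 2.99 and 1.69. Gdf15, a stress cytokine, parted from the rest there: it was at −0.36 in control and 3.29 in mKO, where it reached 425 CPM.

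Endothelial-like cells also differed in activation genes after cisplatin. The endothelial activation list had a median of 0.77 in control (3 of 6 higher, 1 lower) and 0.73 in mKO (4 of 6 higher). Lrg1 was at 5.29 [3.42, 8.35] and 3.14 [1.86, 4.80], the endothelin gene Edn1 at 1.09 and −0.07, and the adhesion gene Vcam1 at −2.09 and 1.22. Between the cisplatin kidneys Vcam1 was at 1.59 and Plvap at −0.44 in mKO over control. Interferon genes, raised in tubules, were lower in 6 of 14 in control endothelial-like cells (median −0.53).

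The sex check genes point to male kidneys in all 4 libraries: Ddx3y had 708, 961, 1058 and 962 UMIs and Xist 1, 0, 0 and 3. Erythroid-like cells were 2.78%, 0.0574%, 5.72% and 0% of kept cells, where a count of 0, taken as 3 cells, allows 0.103%. The largest unnamed cluster, 1, held 1824 cells of mKO saline, 117 of control saline, 0 of control cisplatin and 14 of mKO cisplatin, and carried markers of the proximal and the distal tubule together. Bap1 was seen in 47.3% of all kept cells of mKO saline, and in 4.40%, 7.18% and 5.16% of those of control saline, control cisplatin and mKO cisplatin. Among erythroid-like cells it was seen in 34.1% in mKO saline and in 0 of 88 in control saline.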
